A study of Bacillus subtilis with 6 samples.

How the data were processed

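RNA sequencing was carried out on *Bacillus subtilis* wild type and on a strain deleted for *pnpA*, the gene of polynucleotide phosphorylase, a 3′-to-5′ exoribonuclease. The labels give the genotype of the deletion strain as ΔpnpA::neo, a deletion with a neo insertion. They list 3 libraries per strain, 6 in all. Per the labels' protocols, cells grew in LB at 37 °C to mid-log phase, RNA was extracted with hot phenol, and rRNA was removed with a bacterial depletion kit before standard Illumina library construction. The submitters' processing notes name CASAVA, Bowtie2, SAMtools and bedtools. Their versions, settings and roles, the genome build and the strandedness of the counting are not given in the sources used here. Without strand information, reads of overlapping or antisense genes cannot be told apart.

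A single table of 4176 genes was used. Its expression level is a coverage signal that the authors deposited as a single value per gene and strain, and their scaling is not given in the sources used here. The 5′-to-3′ ratio is, per the file headers and the series' design text, the ratio of read coverage in the 5′ proximal part of a gene to that in its 3′ proximal part, again a single value per strain; the size of these parts is not given. Each p-value is the authors' own and unadjusted, and the test behind it is not given in the sources used here. Fold columns that the authors deposited equalled the quotient of the strain values within a relative tolerance of 1e-06 in 4092 genes. The other 84 genes are listed at 0 in every value column, p-values included, and were left out. No value per library is in the table, so no SD, standard error or replicate comparison could be computed, and all levels and ratios below are the authors' values. Read depth is unknown, since coverage values keep no counts, and no counting interval or floor is given. The labels do not say whether the libraries came from separate cultures, so the authors' p-values may measure technical spread only.

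The design fixed before the data were examined foresaw limma on values per library without a replicate block, camera tests of gene lists and left-out replicates. With a single value per strain none of these was run. For such a table that design foresaw no test, only the log2 ratio as a description. The calls, list percentiles and other tests below depart from it. Calls rest on the authors' p-values, adjusted here with the Benjamini-Hochberg method over the tested genes; a gene was called at an adjusted p under 0.05. Genes with a mean of the 2 strain levels under 1 were left out, a limit that had been written for values per library and was carried over. This left 2107 genes, 469 of them at a level of 10 or more. Adjusted p-values inherit whatever the authors' test assumed. No pseudocount was added for the fold, which was the deletion level over the wild-type level. The median tested gene had a log2 change of -0.22, a fold of 0.859, so the medians of gene lists are given relative to it.

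Of the gene lists, 23 were fixed before the data were examined. Their members were matched on the table's symbols, then on RefSeq symbols and synonyms of the same locus tag (assembly ASM904v1; 4173 locus tags found). Of 817 listed names, 50 matched no gene or more than 1, among them older names of genes already matched. Coordinates are those of the table, 1-based; its build is not named. Gene lengths were multiples of 3 in 99.95% of genes, so they are coding lengths. For each list with 5 or more tested members, the median change was placed among 10000 random lists of the same size matched on level in 10 strata. This percentile describes these strains and is not a p-value, because genes of a list often share an mRNA. Counts of called members are given over all tested genes and adjusted over the list alone. Neighbouring genes on the same strand less than 50 nt apart were compared by the difference of their log2 changes, upstream minus downstream, with 95% bootstrap intervals from 2000 draws over pairs.

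Named genes were chosen by a rule set before the data were examined: *pnpA* and its neighbours; the 10 highest and 10 lowest log2 changes in level and in 5′-to-3′ ratio above the 25th percentile of level over tested genes (1.98); the 4 members of each list with the smallest p; and 13 genes of motility, biofilm, RNA decay and competence listed by name. For the highest and lowest changes, the rule's form for a table without a test was used, which sets no limit on p. Genes that were not called could therefore be named. The list members were still picked by p, here the authors' p-values, so 2 forms of the rule were mixed. Genes named outside this rule are said to be chosen after their values were seen. The steps were tested on simulated data for the 2107 genes with 3 libraries per strain. There, 34% of genes raised 2-fold and 96% of genes raised 4-fold were recovered, 3.70% of calls were false, and 5.75% of random lists fell outside the central 95%. An earlier run of that test with fewer random lists gave 8%, and the number was raised for precision. The simulated calls came from t-tests on values with an assumed spread, whereas the calls reported here rest on the authors' p-values. The shares of recovered and false calls therefore do not carry over to the reported calls. The simulated lists drew genes independently, unlike lists whose genes share an mRNA. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used. Alternatives were no filter, a filter 10 times stricter, pseudocounts of 0.01, 0.1 and 1, scaling to the median gene, other thresholds, random lists matched also on length, a single gene per run of neighbouring list members, and other gaps between neighbours.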

Results

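Total RNA depleted of rRNA was sequenced from wild-type *B. subtilis* and from a *pnpA* deletion strain, each with 3 libraries, during mid-log growth in LB at 37 °C. The deposited table gives a single expression level per gene and strain, with no replicate error, so each level, fold and 5′-to-3′ ratio below stands without an SD, and significance rests on the authors' p-values after adjustment here. Among all genes with values, levels ran from 0.00630 to 1037.5 in the wild type and from 0.0183 to 733 in the deletion strain. The 10 highest genes held 15.3% and 14.8% of the summed level.

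The targeted gene was examined first. *pnpA* (BSU16690, plus strand, positions 1739383 to 1741500) had a level of 22.9 in the wild type and 3.16 in the deletion strain, 7.25-fold lower (adjusted p = 0.00093). The coverage left in the deletion strain lay near the 5′ end: the 5′-to-3′ ratio of *pnpA* was 0.770 in the wild type and 105.9 in the deletion strain (adjusted p = 0.0095). *ylxY* and *mlpA*, the next genes on the same strand, also had lower levels. *ylxY* stood at 1.72 and 0.0585, with a mean level under the limit for testing. *mlpA* fell 17.2-fold, from 2.21 to 0.128 (adjusted p = 0.00079). For these adjacent genes, a local effect of the neo insertion cannot be told apart from an effect of losing the enzyme. Upstream, *rpsO*, the gene of ribosomal protein S15, had levels of 558 and 369 (adjusted p = 0.074), *ribC* had 4.58 and 4.40 (adjusted p = 0.55), and *truB*, a tRNA pseudouridine synthase gene, rose 1.76-fold (adjusted p = 0.0035). Of the 5 tested genes next to *pnpA*, 1 rose and 1 fell, also when adjusted over the list alone, and their median lay at percentile 29.4 of random lists. Further downstream on the same strand the untested gene *ymxH* had levels of 0.253 and 0.225, *spoVFA*, also untested, was at 0.163 in the wild type and 1.85-fold higher in the deletion strain (adjusted p = 0.0080 without the filter), and *dapG* had levels of 7.42 and 5.59 (adjusted p = 0.080).

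Comparing transcript levels asked which mRNAs differ in abundance without polynucleotide phosphorylase. Motility, iron uptake and pyrimidine synthesis genes were lower in the deletion strain, and tryptophan synthesis genes were higher by more than 10-fold. Of 2107 tested genes, 445 rose and 753 fell, and 909 were not called. Changes of at least 2-fold were seen in 182 of the risen and 392 of the fallen genes. Without the filter on low levels 1019 genes rose and 1063 fell, by at least 2-fold in 585 and 564 of them.

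**Figure D1:**
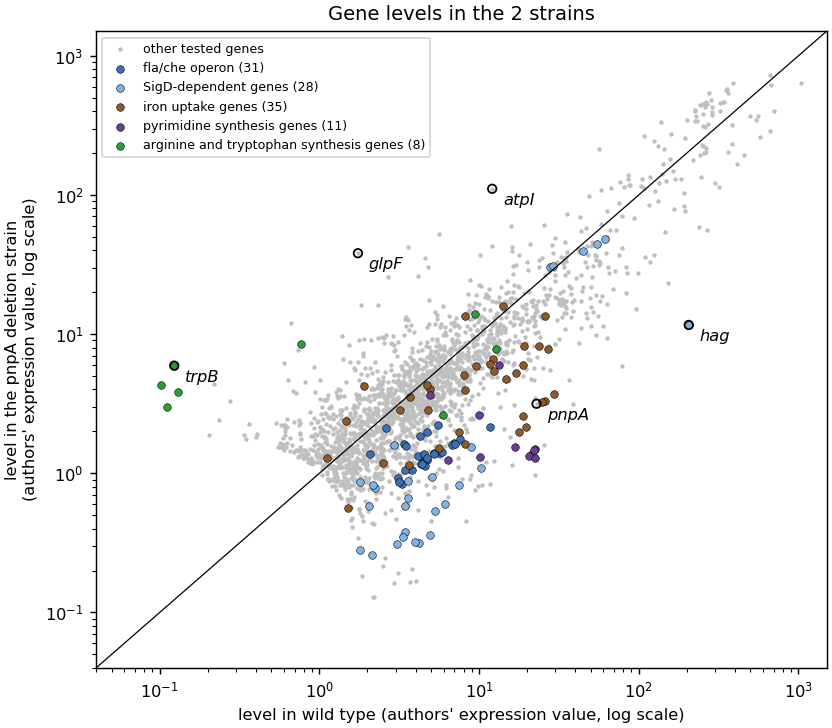
Expression level of each tested gene in the wild type (x axis) and in the *pnpA* deletion strain (y axis), both as the authors' values on log scales, with the line of equal levels. Coloured points are 5 gene lists, with the number of tested genes in parentheses; *hag* lies at 205.5 and 11.6, and *trpB* at 0.123 and 5.94.

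Flagellar and chemotaxis genes were lower as a group. In the fla/che operon, which encodes the flagellar basal body, chemotaxis proteins and the sigma factor SigD, 30 of 31 genes fell, or 31 adjusted over the list alone. Their median was 3.15-fold lower than that of the median tested gene, below all 10000 random lists. *sigD* itself fell 3.67-fold, from 4.69 to 1.28 (adjusted p = 0.0019), and *cheY*, the chemotaxis response regulator, fell 5.50-fold (adjusted p = 0.0020). Among SigD-dependent motility, chemotaxis and autolysin genes, 23 of 28 fell, over all genes and adjusted over the list alone, and the median was 5.05-fold lower relative to the median gene. Under a filter 10 times stricter, where only *hag* and *dltA* to *dltE* were left, their log2 median was -0.23, above the -0.35 of the median gene. The flagellin gene *hag* fell 17.7-fold, from 205.5 to 11.6 (adjusted p = 0.00093). The autolysin genes *lytF* and *lytC* fell 9.01-fold and 4.03-fold. The 5 members not called were *dltA* to *dltE*, which modify teichoic acids and were named after their values were seen; *dltA* had levels of 28.0 and 30.5.

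Genes of the motility and biofilm switch moved in both directions. *slrA*, a small regulator of that switch, rose from 1.82 to 5.13 (adjusted p = 0.029). *sinR*, the repressor of matrix genes, fell 2.13-fold (adjusted p = 0.0044), and its antagonist *sinI* fell 2.06-fold (adjusted p = 0.0081). *yuaB*, the gene of the biofilm surface protein BslA, fell 3.17-fold (adjusted p = 0.0011). Only these 4 of 23 matched biofilm genes were at a testable level, too few for a percentile. *slrR* stood at 0.0365 and 0.0834. Without the filter, 10 of the 23 rose and 3 fell, also when adjusted over the list alone, with a median at percentile 99.1.

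Pyrimidine and iron genes held the lowest medians besides motility. All 11 pyrimidine synthesis genes were tested; 6 fell over all genes and 10 adjusted over the list alone. Their median was 9.37-fold lower relative to the median gene. The largest fold was that of *pyrE*, from 22.4 to 1.30, which missed the threshold (adjusted p = 0.069), while *carB* (BSU15520, the large carbamoyl phosphate synthase subunit of this pathway) fell 15.5-fold (adjusted p = 0.032) and *pyrC* fell 7.68-fold (adjusted p = 0.0066). Of 35 iron uptake genes of the Fur regulon, 24 fell and 1 rose, over all genes and adjusted over the list alone. The median was 1.93-fold lower relative to the median gene and below all 10000 random lists. *feuA*, the binding protein for iron-loaded bacillibactin, fell 9.01-fold (adjusted p = 0.00071), and *dhbF*, which assembles bacillibactin, fell 9.05-fold (adjusted p = 0.015). The exception was *yfmE*, which rose 2.23-fold (adjusted p = 0.012).

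TCA cycle, glycolysis and ATP synthase genes were each set against random lists. In the TCA cycle 8 of 12 genes fell, or 9 adjusted over the list alone, and the median was 1.76-fold lower relative to the median gene, at percentile 1.36. With a single gene per run of neighbours 7 of these genes were left, and their median lay inside random lists, at percentile 2.90. *fumC*, fumarase, fell 4.89-fold (adjusted p = 0.0020), and *sucD* fell 2.47-fold (adjusted p = 0.0024). In glycolysis and pyruvate dehydrogenase, 3 genes rose and 5 fell among 17, also when adjusted over the list alone, at percentile 64.0. *cggR*, the repressor of the glycolytic operon it heads, rose 3.75-fold from 56.5 to 212 (adjusted p = 0.0021), whereas the next gene, *gapA*, chosen after its values were seen, had levels of 256 and 200 (adjusted p = 0.15). *pgi* fell 4.39-fold and *fbaA* fell 2.79-fold. In the ATP synthase operon the first gene, *atpI*, rose 9.17-fold from 12.1 to 111 (adjusted p = 0.0054), while *atpB* after it stood at 29.6 and 29.4 (adjusted p = 0.94). *atpE* fell 1.48-fold (adjusted p = 0.011). The other 7 of 9 ATP synthase genes were not called, with the same counts adjusted over the list alone; mean and median of this list differed in sign (0.20 and -0.02 on the log2 scale), and the median turned positive relative to the median gene, at percentile 66.4.

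Tryptophan synthesis genes were among the most raised genes. *trpB* rose 48.1-fold, from 0.123 to 5.94 (adjusted p = 0.0022), *trpF* 42.8-fold, *trpC* 29.4-fold, *trpD* 27.0-fold and *trpA* 11.1-fold, all called. In the list of arginine and tryptophan synthesis genes 6 of 8 tested members rose and 2 fell, over all genes and adjusted over the list alone, and the median lay above all 10000 random lists. *trpS*, the tryptophanyl-tRNA synthetase, fell 2.24-fold (adjusted p = 0.0040). *trpA*, *trpB*, *trpF*, *trpC* and *trpD* passed the minimum mean level only through their level in the deletion strain, so the filter favoured risen members of this list. Without the filter 12 of 20 rose and 2 fell, also adjusted over the list alone, and the median log2 change was 1.10 in place of 4.11, at percentile 99.96.

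**Figure D2:**
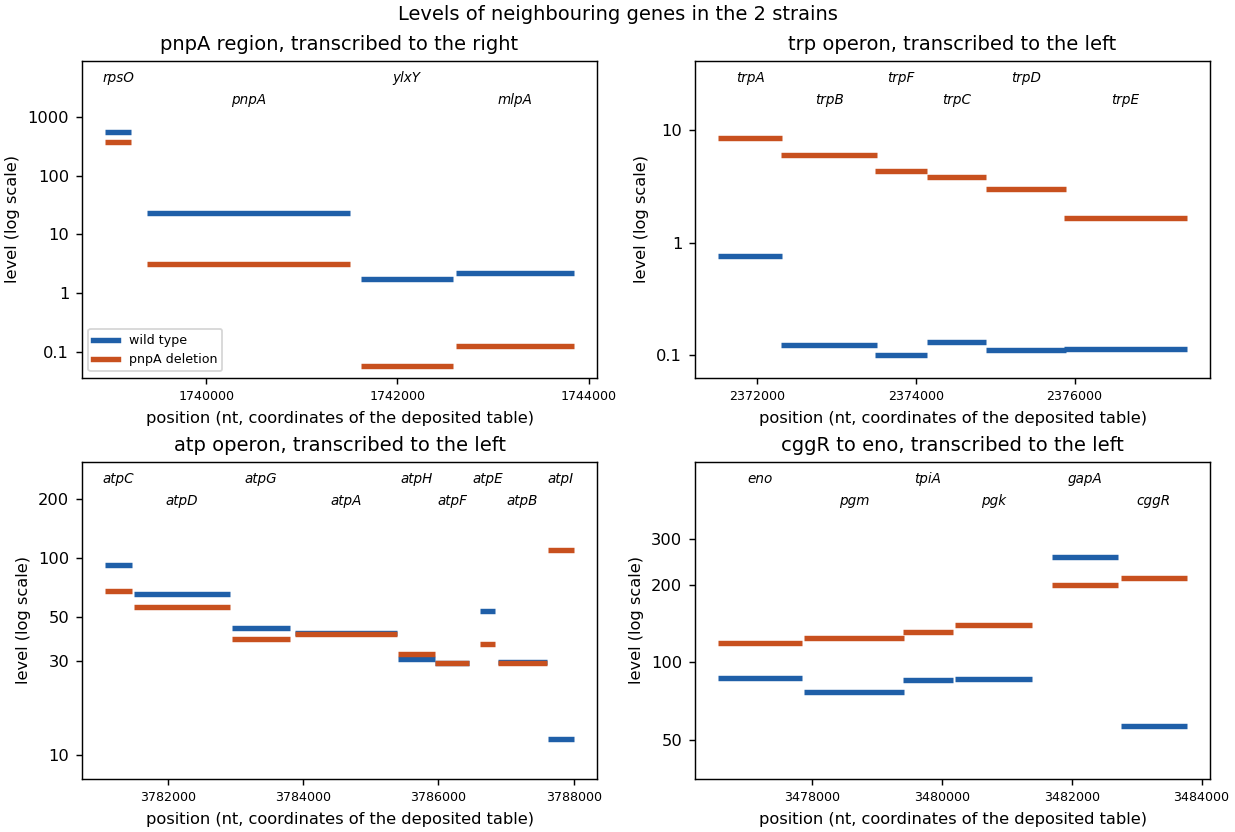
Levels of neighbouring genes in the wild type (blue) and the *pnpA* deletion strain (orange), as the authors' values on log scales, against the positions the table gives. *atpI* and *cggR*, each the first gene of its group, were higher in the deletion strain (111 and 212) than in the wild type (12.1 and 56.5), and *ylxY* and *mlpA*, after *pnpA*, were lower.

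Genes of glycerol, mannose and gluconate use, which formed no list fixed beforehand, were among the most raised. *glpF*, the glycerol facilitator, rose 21.9-fold from 1.74 to 38.1 (adjusted p = 0.0027), and *glpD*, glycerol-3-phosphate dehydrogenase, rose 11.7-fold (adjusted p = 0.00060). *manR*, the regulator of mannose use, rose 18.2-fold (adjusted p = 0.0025), *gntK*, gluconate kinase, rose 10.2-fold (adjusted p = 0.0047). *ylbB* and *yhbI* rose 19.8-fold and 10.5-fold. In the wild type *manR*, *gntK*, *ylbB* and *yhbI* stood at 0.662, 0.603, 0.219 and 0.735. These genes passed the minimum mean level only through their level in the deletion strain. Among the most lowered were *cotC*, a spore coat gene, 23.8-fold from 4.02 to 0.169 (adjusted p = 0.038), *phrK* and *rapK*, a signalling peptide gene and its phosphatase gene, 23.1-fold and 18.6-fold, *xylA*, xylose isomerase, 18.1-fold (adjusted p = 0.00093), and *ybdZ*, 16.0-fold (adjusted p = 0.0089). *pyrD* and *pyrF* were 14.9-fold and 15.4-fold lower and were not called.

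Ribosomal protein, ribonuclease and SigB genes had raised medians. Of 52 ribosomal protein genes 21 rose and 3 fell (20 and 3 adjusted over the list alone); *rpsJ* rose 2.42-fold from 139 to 335 (adjusted p = 0.0036) and *rpsS* 1.49-fold (adjusted p = 0.0044). Their median was 1.53-fold higher relative to the median gene, at percentile 99.99. With a single gene per run of neighbours the log2 median was 0.04 in place of 0.39, at percentile 87.5. Relative to the median gene it was 0.26 in place of 0.61. Among ribonucleases and RNA helicases, 8 of 18 rose and 3 fell, also adjusted over the list alone, at percentile 99.0. *rnhB* rose 2.62-fold (adjusted p = 0.0016), *rnhC* 2.03-fold, *rph* 1.58-fold and *rnjB* 1.26-fold (adjusted p = 0.012), and *yhaM* fell from 5.23 to 3.26 (adjusted p = 0.0028). Not called were *rnjA* (13.9 and 15.9), *ymdA*, the gene of RNase Y (33.3 and 32.2), *rnr* (5.34 and 7.52) and *cshA* (17.7 and 21.9). Of 59 SigB general stress genes 25 rose and 2 fell (21 and 2 adjusted over the list alone), with a median 1.58-fold higher relative to the median gene, above all 10000 random lists. Under a filter 10 times stricter their log2 median was 0.11 in place of 0.44, while that of the median gene was -0.35 in place of -0.22. *sigB* rose 2.03-fold from 35.7 to 72.7 (adjusted p = 0.0072), and *yvgN* fell 3.32-fold.

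SPbeta prophage and purine synthesis genes lay below the central 95% of random lists, and SigW and SigX, PBSX, early sporulation and heat shock genes lay inside it. SPbeta prophage genes had 7 of 22 tested members lower and none higher, also adjusted over the list alone, with a median below all 10000 random lists; *bdbB* fell 7.93-fold (adjusted p = 0.0071). Without the filter, where 135 of these genes were measured, 17 rose and 15 fell (6 and 5 adjusted over the list alone). Their median change was then positive and lay above the central 95% of random lists, at percentile 99.9. Purine synthesis genes lay at percentile 2.49, with 7 of 16 lower and 1 higher (6 and 1 adjusted over the list alone); *glyA* fell 3.33-fold (adjusted p = 0.0043). SigW and SigX genes had 22 of 45 lower and none higher, also adjusted over the list alone, at percentile 7.45; *racX* fell 3.38-fold. With a single gene per run of neighbours, 13 of 24 of them were lower, and the median lay outside random lists, at percentile 1.33. PBSX prophage genes had 15 of 25 lower (16 adjusted over the list alone) and none higher, at percentile 13.9; *xkdM* fell 1.99-fold. Early sporulation and cannibalism genes had 2 higher and 4 lower of 14, also adjusted over the list alone, at percentile 5.32; *spo0B* rose 4.31-fold and *spo0A*, the master regulator of sporulation, fell 2.54-fold (adjusted p = 0.0021). Heat shock genes had 1 higher and 8 lower of 18, also adjusted over the list alone, at percentile 27.4; *groEL* fell 4.79-fold from 267 to 55.8 (adjusted p = 0.0017) and *clpP* 3.55-fold.

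Cold shock, competence, sulfur and synthetase genes lay inside the central 95% of random lists. Cold shock genes had 4 higher and 1 lower of 16 (2 and 1 adjusted over the list alone), at percentile 77.6, with *cspB* at 1038 and 637 (adjusted p = 0.068). Competence genes had 3 higher and 3 lower of 11, also adjusted over the list alone, at percentile 73.4; *comK*, the competence regulator, stood at 0.163 and 0.212, under the limit for testing. Without the filter 15 of 27 competence genes rose and 4 fell (15 and 5 adjusted over the list alone), with a median at percentile 99.7, outside random lists. Sulfur amino acid genes had 3 higher and 4 lower of 11, also adjusted over the list alone, at percentile 70.8; *cysK* fell 3.61-fold. Aminoacyl-tRNA synthetase genes had 4 higher and 7 lower of 21, also adjusted over the list alone, at percentile 71.8. The medians of these 4 lists and of the glycolysis list were slightly negative and became positive relative to the median gene.

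**Figure D3:**
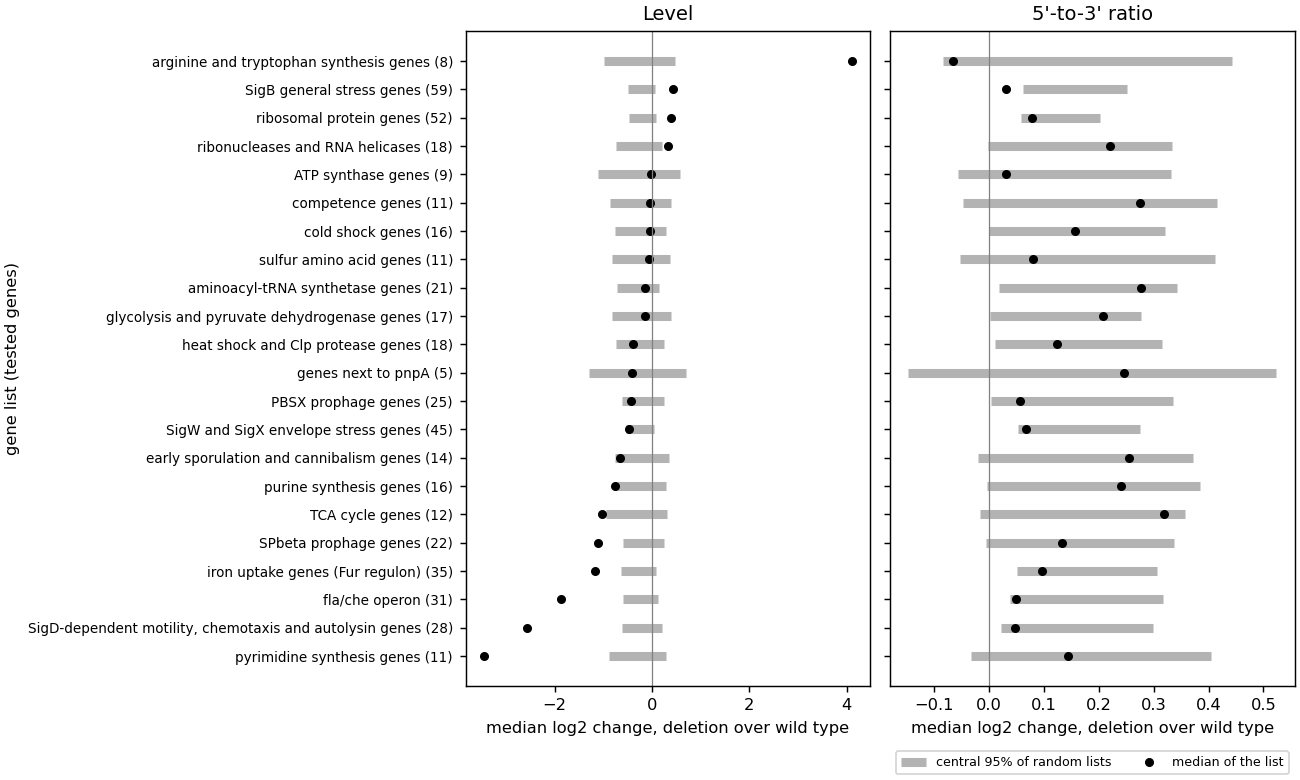
Median log2 change (deletion over wild type) of 22 gene lists in level (left) and in 5′-to-3′ ratio (right); points are medians, and grey bars span the central 95% of 10000 random lists matched on level. For level, 11 lists lie outside their bar, 4 above and 7 below; for the ratio, 1 list, the SigB genes, lies outside, at percentile 0.125. By chance 1.1 of 22 lists would be expected outside if the genes of a list changed independently. Genes of a list often share an mRNA, so more lists could fall outside by chance.

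The series was designed to find mRNA decay intermediates by comparing coverage near the 5′ and 3′ ends of genes. In the wild type coverage leaned to the 3′ end: the median 5′-to-3′ ratio in the authors' deposited table was 0.836, with quartiles of 0.637 and 1.06. Of 2107 genes, 643 had significantly less 5′ than 3′ coverage and 156 significantly more. In the deletion strain the median was 0.929, and the numbers were 320 and 155. These counts rest on the authors' p-values within each strain. By size alone, a ratio above 2 was seen in 46 genes in the wild type and 111 in the deletion strain. A ratio below 0.5 was seen in 257 and 157. The lean was larger in long genes, with wild-type medians of 1.03 among the shortest of 4 equal bins (63 to 435 nt) and 0.648 among the longest (1131 to 10764 nt).

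Between the strains, ratios shifted toward the 5′ end in the deletion strain. The ratio was higher in the deletion strain for 1487 genes (70.6%), and the median log2 change was 0.16 (95% bootstrap interval over genes 0.14 to 0.18). It rose in 173 genes and fell in 25 at an adjusted p under 0.05, by at least 2-fold in 44 and 11 of them. At an adjusted p under 0.01 only 10 and 6 were left. Among the 173, the median ratio went from 0.597 to 0.934, 150 lay below 1 in the wild type and 100 in the deletion strain, and the median coding length was 1209 nt against 756 nt for all tested genes.

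**Figure D4:**
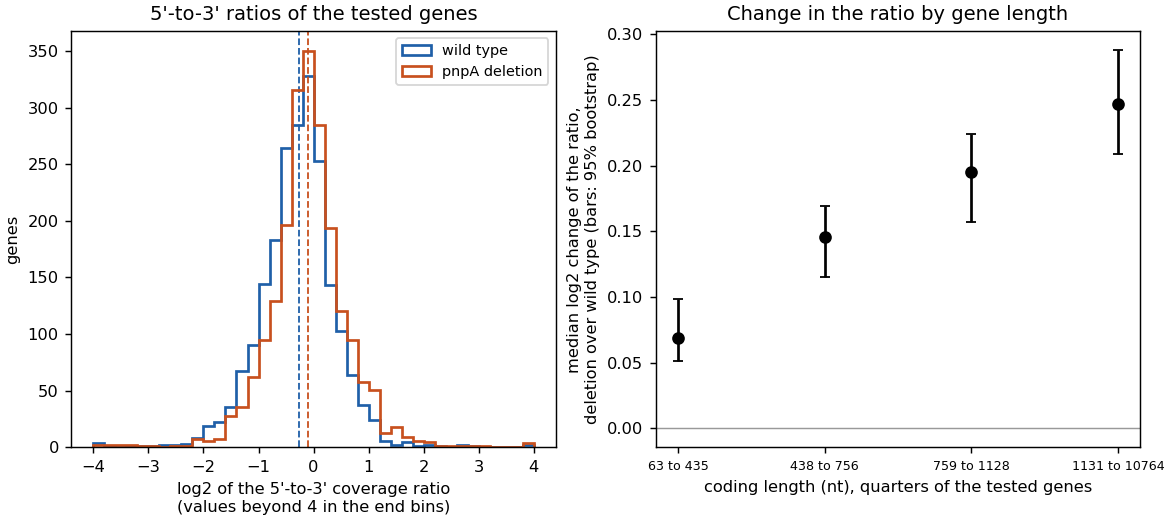
Left, distribution of the log2 5′-to-3′ coverage ratio over 2107 tested genes in each strain, with dashed lines at the medians (ratios of 0.836 and 0.929). Right, median log2 change of the ratio in 4 equal bins of coding length with 95% bootstrap intervals, from 0.07 in the shortest to 0.25 in the longest genes.

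Besides *pnpA*, the largest rise in the ratio that passed the threshold under the fixed rule was that of *rapK*, a phosphatase gene. It went from 0.00811 to 0.0837 (10.3-fold, adjusted p = 0.026), and *trpA* went from 0.116 to 0.727 (6.27-fold, adjusted p = 0.048). Low levels lie behind a ratio of each: *rapK* stood at 0.206 in the deletion strain, and *trpA* at 0.762 in the wild type. In the wild type *rapK* stood at 3.82, beside its paired gene *phrK*, which had levels of 22.4 and 0.971. Reads of overlapping *rap* and *phr* genes cannot be told apart, and their share in this ratio was not tested. *yabE*, a cell wall-binding protein gene, went from 0.386 to 2.18 (adjusted p = 0.0095), *atpI* from 0.909 to 4.80 (adjusted p = 0.00085), *ygaE* from 0.844 to 4.28 and *yukJ* from 0.924 to 4.21. Within the SPbeta list, *sunT*, the transporter of the bacteriocin sublancin, went from 1.09 to 8.17 (adjusted p = 0.0095). *rapA*, *comQ* and *rapF* were 10.4-fold, 5.82-fold and 5.04-fold higher without passing the threshold (adjusted p = 0.11, 0.33 and 0.16). Falls were largest in *degR*, from 0.661 to 0.0790 (adjusted p = 0.031), *pabB*, an aminodeoxychorismate synthase gene, from 0.259 to 0.0357 (adjusted p = 0.00091), *ytzK*, from 0.545 to 0.0830, and *yrrT*, from 0.0441 to 0.0107 (adjusted p = 0.010). *ykuK* and *fni* went from 4.36 to 1.07 and from 7.48 to 2.78 (adjusted p = 0.0050 and 0.0031).

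Only SigB genes stood apart from random lists in the ratio, and which other lists did depended on the settings. SigB general stress genes had a median log2 change of 0.03, below nearly all random lists (percentile 0.125), with 3 genes higher and 1 lower (2 and 1 adjusted over the list alone); the ratio of *sigB* fell from 1.21 to 0.736 (adjusted p = 0.026). Aminoacyl-tRNA synthetase genes held the most calls: 8 rose and 1 fell (10 and 1 adjusted over the list alone), at percentile 89.3. The ratio rose 2.51-fold in *valS* (adjusted p = 0.030), 1.92-fold in *leuS* (adjusted p = 0.011), 1.86-fold in *ileS* and 1.83-fold in *lysS*. With a single gene per run of neighbours, the synthetase, TCA cycle and iron uptake lists lay outside, at percentiles 98.5, 97.7 and 97.8. With random lists matched on length the synthetases lay at 63.7, and the arginine and tryptophan list lay outside, at 1.99. Without the filter the TCA cycle, ribonuclease, and arginine and tryptophan lists lay outside, at 97.8, 98.9 and 0.470. TCA cycle genes lay at percentile 94.6 with 3 higher, also adjusted over the list alone, among them *fumC*, 1.44-fold (adjusted p = 0.039), and heat shock genes at percentile 37.0 with 4 higher (5 adjusted over the list alone), among them *groES*, 2.26-fold (adjusted p = 0.021). Ribonuclease genes, at percentile 77.5, had 3 higher and 1 lower, also adjusted over the list alone; *rnjB* rose 1.37-fold (adjusted p = 0.0495) and *mrnC* fell to 0.755 of its wild-type ratio. In the other lists at most 2 genes rose and at most 2 fell over all genes; adjusted over the list alone, 6 iron uptake and 5 glycolysis genes rose. The fla/che operon, whose levels fell, had a median ratio change of 0.05 with 1 lower, *fliZ* (adjusted p = 0.036), and none adjusted over the list alone.

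Over all tested genes, a change in ratio did not go with a change in level. Of the genes called for the ratio, 103 were also called for level (52.0%), against 57.4% of the other genes (odds ratio 0.81, two-sided Fisher's exact p = 0.15, across genes, which are not independent). Among the genes whose ratio rose, 39 rose and 48 fell in level. The 25 genes whose ratio fell leaned the other way, with 10 higher and 6 lower in level. Of all tested genes, 445 rose and 753 fell in level. This lean of a small group was not tested. Across genes, Spearman's rho between the 2 log2 changes was 0.0047; genes are not independent replicates. At an adjusted p under 0.01 the odds ratio was 2.15 (two-sided Fisher's exact p = 0.17), with 8 of 16 genes called for the ratio also called for level.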

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

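In 6 genes the 5′ and 3′ coverage differed significantly in both strains but in opposite directions, always with less 5′ than 3′ coverage in the wild type and more in the deletion strain. For 4 of these the difference between the strains also passed the threshold. *pnpA* had the largest, with a ratio 137.6-fold higher in the deletion strain, where the gene is disrupted. *yabE* followed at 5.64-fold (from 0.386 to 2.18). *cotZ*, a spore crust gene whose level was 0.204 in the wild type and 1.88 in the deletion strain, was at 1.99-fold (adjusted p = 0.036), and *ymfH*, a peptidase-like gene, at 1.40-fold (adjusted p = 0.044). In *ywmB* and *fhuC* the ratios were 4.33-fold and 1.32-fold higher, and the difference between strains missed the threshold (adjusted p = 0.062 and 0.076). *cotZ*, *ymfH*, *ywmB* and *fhuC* were chosen after their values were seen.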

How the results depend on the processing

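No paired analysis was possible because the table has a single value per strain; for the same reason left-out replicates, limma without trend, estimated correlations in gene lists and other splits of the 6 libraries were not run. A value per transcription unit was not run, as the table lists genes, nor was a pseudocount on the 5′ and 3′ values, which are not given. Thresholds other than those planned, single genes per run, matching on length and other gaps were chosen after seeing the data. Scaling to the median gene cannot change which genes are called, since the authors' p-values stay, and tests no call; by sign it gave 448 and 750 genes in level, and 173 and 25 in ratio. Without the filter, 1019 genes rose in level and 983 had less 5′ than 3′ coverage in the wild type; 4 lists lay outside random lists on the ratio; and the SPbeta median turned to 0.49. A filter 10 times stricter tests fewer genes: 96 rose and 192 fell in level, 41 rose and 6 fell in ratio, 96 and 35 had less and more 5′ than 3′ coverage in the wild type, 4 of 13 testable lists lay outside on level (11 of 22 before), and the median ratio change was 0.14. Under that filter the SigD-dependent list had a median of -0.23. At an adjusted p under 0.01, 240 rose and 432 fell in level and 10 rose and 6 fell in ratio. The odds ratio of the overlap moved across 1, to 2.15 (two-sided Fisher's exact p = 0.17). It rests on 16 genes called for the ratio and was not told apart from 1 at either threshold. The cause of the move was not tested. At an unadjusted p under 0.05, 473 and 87 genes rose and fell in ratio. With a single gene per run of neighbours, 7 of 17 testable lists lay outside on level and 4 on the ratio, and the pyrimidine, fla/che and arginine and tryptophan lists had too few genes; matched on length, 2 did so on the ratio. Pseudocounts of 0.01, 0.1 and 1 gave *pnpA* log2 changes of -2.85, -2.82 and -2.52. With the largest, 109 genes were at least 2-fold higher and called. In all, 75 alternative values were computed. Unknown depth limits the ratios of low genes most.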

Other observations

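The tests on low levels and on genes called for the ratio in neighbouring genes, and that on genes without a change in level, were set before their results were seen; the filter behind the test of the ratio at a level of 10 or more was planned, but its bound was set afterwards. All other tests and the genes named in this part beyond the fixed rule were chosen after the values were seen. What a library-wide difference in coverage would give was also reworded after its values were seen.

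Neighbours of the raised glycerol, mannose and gluconate genes were examined, without a test of carbon use as a group. *glpK*, glycerol kinase, rose 9.23-fold from 5.65 to 52.1 (adjusted p = 0.0040), next to *glpF* and *glpD*. In the mannose operon *manP* rose 9.64-fold and *manA* 7.64-fold. *gntR*, the gluconate repressor, rose 10.3-fold, while *gntP*, further along the operon, rose 2.03-fold with a 5′-to-3′ ratio of 0.0955 in the wild type and 0.416 in the deletion strain (adjusted p = 0.028). *alsS* and *alsD*, which make acetoin, rose 12.0-fold and 7.39-fold. *ribD*, a riboflavin gene, rose from 1.39 to 9.76 and *ribE* rose 3.02-fold. Lower were *pstS*, the phosphate-binding protein, 22.4-fold (adjusted p = 0.010), the subtilosin gene *sboA*, 18.2-fold, and *xylB*, 13.0-fold. The mean of the 2 strain levels was not above 1.98 in *alsS*, *gntR*, *pstS* and *sboA*. Their folds therefore rest on a low level in the lower strain. *katA*, catalase, and *ahpC*, alkyl hydroperoxide reductase, fell 5.16-fold and 3.08-fold.

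Genes of response regulator phosphatases and their inhibitory peptides form overlapping pairs. In all 8 *rap*-*phr* pairs with values the *rap* gene was higher relative to its *phr* gene in the deletion strain, by a median of 0.93 on the log2 scale. The 5′-to-3′ ratio within the *rap* gene was higher in 8 of 8, with log2 changes from 0.88 to 3.39. Because the genes overlap, these counts are not independent. Among all 1460 unfiltered pairs less than 50 nt apart, 66.6% went the same way, and 66.1% of unfiltered genes had a higher ratio. Without the filter 2 of the 8 *rap* genes were called for the ratio. The steepest was *rapA* against *phrA*: *rapA* rose from 1.81 to 16.1 and *phrA* stood at 1.24 and 1.07. In *rapC* and *phrC* the levels went from 3.98 to 2.57 and from 22.4 to 3.48.

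The first pattern was the higher 5′-to-3′ ratio in the deletion strain. Noise in poorly covered genes is argued against by the 469 genes at a level of 10 or more, where the median log2 change was 0.140 (95% bootstrap interval 0.118 to 0.168). A change in level is argued against by the 417 genes with an unadjusted level p above 0.2 in the authors' deposited table, with a median of 0.167 (0.127 to 0.208). A library-wide difference in coverage along the RNA, from RNA quality or library preparation, may contribute: it would grow with the distance between the ends, and the median change was 0.247 (0.209 to 0.288) in the longest 527 genes against 0.07 in the shortest 528. Fragments left by the loss of a 3′ exonuclease could give the same growth, and without values per library this biological explanation stays open and untested.

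The second pattern concerned neighbouring genes. In 734 pairs less than 50 nt apart the upstream gene changed more upward than the downstream gene in 71.4%, by a median of 0.18 on the log2 scale (0.14 to 0.21). Low levels are argued against by the 157 pairs with both genes at 10 or more (median 0.141, 0.0930 to 0.199), a property of any neighbours by pairs 150 to 1000 nt apart (-0.0467, -0.287 to 0.0641; pairs 50 to 150 nt apart, at 0.0997, -0.0785 to 0.194, overlapped the close pairs and decide nothing), and a few genes with a changed ratio by the 632 pairs without any such gene (0.154, 0.118 to 0.192). A library-wide slope in coverage was not tested here and stays open beside slower decay of 5′ parts of operon mRNAs, an untested hypothesis that may hold for pairs such as *atpI* and *atpB* or *cggR* and *gapA*. The largest opposite difference was between *sboX*, 16.9-fold lower, and *albA*, at 2.35 and 2.16.

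The third pattern was a higher level of weakly expressed genes in the deletion strain. In the 410 lowest genes without the filter the median log2 change was 0.91, and in the 410 highest it was -0.34. A single scaling factor between strains is argued against by the difference of 1.26 (1.11 to 1.38). An even background of reads in the deletion strain could contribute and stays open: the median difference in level was 0.0350 (0.0255 to 0.0476) in the 409 next-lowest genes, overlapping 0.0285 (0.0255 to 0.0327) in the lowest. In the following bins of 409 genes it was 0.0144 (-0.00146 to 0.0380), an interval that includes 0, then 0.0574 (0.0148 to 0.0928) and -0.0614 (-0.157 to -0.00725), so the difference was not even beyond the lowest levels. Whether such reads come from DNA, from low transcription across the genome or from slower decay stays open, and no biological explanation was tested.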
